A study of Danio rerio with 36 samples.

How the data were processed

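RNA sequencing was used to measure transcript levels in zebrafish eyes. The series holds 36 samples in 12 groups of 3. At 1 month of age, lrp2 mutants and wild-type fish were each sampled as whole eyes, retinal pigment epithelium (RPE), retina, and sclera with choroid, which gave 24 libraries. At 5 days post-fertilization, whole larval eyes of 2 transgenic lines were sampled, each beside its own control, which gave 12 libraries. The first line carries a heat-shock promoter in front of a bmp4 fusion with green fluorescent protein and the other the same kind of promoter in front of shha. Per the labels' protocols, fish were kept at 28.5 degrees under 14 h of light and 10 h of dark, eyes were dissected and stored in RNAlater, and RNA was taken up in Trizol, checked on a BioAnalyzer and sequenced after a low-input Illumina preparation. The labels used here give no scheme of heat shock for the larval lines and do not say that the 3 libraries of a group come from separate animals, so every p-value below measures only the spread between these libraries, which may be technical.

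For the 1-month libraries and for each larval line, the authors deposited expected counts and TPM, transcript levels scaled to a common total per library, for 31916 Ensembl gene identifiers in every library. FPKM values that the authors deposited for the 1-month libraries served only to derive gene lengths from the counts. Values per transcript were not used here. Per the submitters' processing notes, Bowtie2 and HISAT were among the tools and GRCz10 was the genome build. Versions, the role of each tool, the counter, the annotation release and the handling of strand are not given in the sources used here. Reads of near-identical gene copies (the crygm crystallins, the major histocompatibility, nlr, sult and pimr families), of overlapping genes and of antisense partners may therefore have been divided among them in ways the counts do not show, and values of single members of those families are uncertain. Gene symbols came from a table of identifiers, which named 26108 of the 31916 identifiers. The other 5808 held 2.22% of all counts. Symbols in capitals are those of human orthologues, and where several zebrafish genes share such a symbol the Ensembl identifier follows it. A table of gene records of assembly GRCz12tu was used only for older names and for which genes neighbour each other, and no coordinates are printed because the builds differ. The list of mitochondrially encoded genes had 0 members in the tables and was not analysed here.

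Total expected counts lay between 17543328 and 26708423 per library, and 24143 to 25525 genes had at least 1 count. No pair of libraries within a group agreed within counting noise, since the chi-square per degree of freedom of each pair was between 11.9 and 277, so all 36 were counted as samples. The deposited expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, libraries were scaled by TMM, and a quasi-likelihood F test with robust dispersion was run on both groups of a comparison. The two-sided p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were taken from the F statistic. CPM are counts relative to the TMM-scaled library size and are given as mean ± SD over n = 3 libraries unless another n is stated. For a group with 0 counts in all 3 libraries, the fold is a lower bound against a floor of 3 counts over the group, and for a group with 1 to 3 counts the ratio has a 95% exact binomial interval. Both cover counting error only.

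Differences of the lrp2 effect between tissues were interaction contrasts in a fit of all 24 libraries of 1 month, wild-type tissues were compared in a fit of their 9 libraries, and the difference between the larval lines was an interaction contrast over 12 libraries from 2 separately deposited tables. Overlaps of called genes between comparisons were tested per direction with a two-sided Fisher's exact test, and correlations of fold changes are across genes, which are not independent replicates. No library served in both comparisons of any overlap, but the labels do not say whether tissues of a genotype came from the same fish. Same-numbered libraries of sclera with choroid and RPE had correlations of 0.06 to 0.27 in wild type and 0.10 to 0.40 in mutants. Each was best with its own number. So was each library of sclera with choroid and retina (0.01 to 0.1 in wild type, 0.06 to 0.12 in mutants). The same held for mutant RPE and retina (0.04 to 0.11 over 2 pairs), while in wild-type RPE and retina 1 of 3 was best with its own number. The Fisher p-values take genes and comparisons as independent and may be too small.

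Gene lists were written before the data were examined, together with the tests, the alternatives and the rule for named genes. The 44 lists with measured members were LDL receptor family and megalin partners, secretases and processing proteases, BMP ligands and receptors with extracellular regulators, BMP response genes, hedgehog pathway, TGF-beta pathway, Wnt response genes, Notch response, RPE and visual cycle, melanin and melanosome, iridophores, rod phototransduction, cone phototransduction, Müller glia, bipolar cells, amacrine and horizontal cells, retinal ganglion cells, lens crystallins and fibre cells, corneal and surface epithelium, scleral and corneal fibroblast matrix, cartilage, bone, matrix metalloproteases, vascular endothelium, red blood cells, macrophages and microglia, neutrophils, inflammation and interferon, skeletal muscle, myelin, proliferation, heat shock proteins, ER stress, immediate early genes, circadian clock, retinoic acid pathway, cholesterol synthesis, lysosome, intraocular pressure genes, ocular growth and refraction candidates, ribosomal proteins, nuclear oxidative phosphorylation, glycolysis and hypoxia response. Each was tested with camera of limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, and p-values were adjusted over the lists of a comparison. With an estimated correlation no list was called in any of the 6 comparisons, so a list call below compares members with other genes at the preset correlation only. That version of the test rests on the few residual degrees of freedom of 6 libraries and has little power. Its smallest unadjusted p in the bmp4 line was 0.00561. A call lost with it does not show that correlation between members made the call. fry, which tests whether members move on balance 1 way without setting them against other genes, was the other list test. Among the 10 splits of the 6 libraries of each comparison, regroupings that mix the genotypes called up to 22 lists, and this number is given per comparison.

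The text names, for each comparison, the targeted or expressed gene in every library. It then names the 8 largest positive and 8 largest negative log2 fold changes among called genes with a mean of at least 5 CPM in the higher group and no overlap of the groups, without clone names. From each list with a camera adjusted p under 0.05 or at least 3 called members it names called members with the smallest p, at most 4. Where fewer than 5 genes were called, the 5 smallest p are named, and for differences and tissue comparisons the 4 smallest p per direction. Members of the BMP, hedgehog and processing lists could be named at any p. Of the genes the rule selects, some in the retina and sclera are given only in counts, and a few results are not reported here.

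The fits of the 6 comparisons and of the difference between RPE and retina were tested on counts simulated from their libraries, with 100 genes changed 2-fold and 100 changed 4-fold. In the simulated comparisons edgeR recovered 47 and 99 of these genes for whole eyes, 12 and 76 for RPE, 82 and 98 for retina, 43 and 85 for sclera with choroid, 72 and 95 for the bmp4 line, and 0 and 4 for the shh line, over 19720 to 21096 genes tested. False calls made up 8.8%, 11.1%, 8.6%, 10.5%, 7.7% and 0% of calls in the same order, above the nominal 5% in 5 of the 6. The interaction contrast over 23499 genes recovered 29 and 71, with 7.4% false calls. The other interaction contrasts, the comparisons between wild-type tissues and between larval controls, and the fit of all 24 libraries were not simulated. DESeq2 1.42.0 gave 14.7 to 44.6% false calls in these simulations. No effect of the replicate number was simulated.

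Replicate numbers occur in both groups of each comparison, only 2 of them in RPE. Numbers were taken to pair libraries where every same-numbered pair had a correlation above 0.1 between their deviations from the group means, over genes with a mean of at least 20 counts and with a prior count of 2. This held for the bmp4 line (0.52 to 0.67 over 3 pairs) and the shh line (0.25 to 0.40), so a fit with the replicate number as a block is given beside those results where it changed a call or moved a count by over 1.5 times. It did not hold for the lrp2 comparisons. The other alternatives were DESeq2, RLE scaling, no filter on low counts, leaving out 64 crystallin and haemoglobin identifiers, limma on log2(TPM + 1), leaving out each library, and a single fit of all 24 libraries. On the log2(TPM + 1) scale the median of all genes shifted from 0.01 to 0.08 in whole eyes, from 0.03 to 0.15 in RPE, from 0.00 to 0.14 in sclera with choroid and from 0.00 to −0.27 in the shh line, and changes below are relative to the TMM scale. Alternatives added after the data were seen concern only the shh libraries numbered 13.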

Results

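Transcripts were counted in eyes of wild-type zebrafish and of mutants of lrp2, the gene of the large endocytic receptor megalin, and in eyes of larvae that carried a heat-inducible bmp4 or shha transgene. The series title names processing of LRP2 on RPE cells, BMP activity, eye size and refractive error as its subject. There were 12 groups of 3 libraries. Whole eyes, RPE, retina, and sclera with choroid came from lrp2 mutants and wild type at 1 month. The others were larval whole eyes of each transgenic line and its own control at 5 days. Total counts per library were 22499195 to 26155084 for whole eyes, 20037167 to 23224099 for RPE, 17819884 to 23435842 for retina and 17543328 to 24913676 for sclera with choroid. They were 22884531 to 26708423 for the bmp4 set and 22003063 to 26679182 for the shh set.

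The dissected tissues of wild type differed in most genes tested between retina and either other tissue. In RPE against retina, COL8A2, a collagen of basement membranes, was at 223 ± 5.83 CPM against 1.02 ± 0.071 (log2 7.77, SE 0.16). TYRP1 (ENSDARG00000029204), GPR143 and SLC45A2, genes of the melanosome, were higher in RPE by log2 6.87, 5.84 and 7.20. The neuronal genes nrxn1a, YWHAG (ENSDARG00000071658), PCDH11X and CELSR3 were lower by log2 changes of −5.54, −5.65, −4.52 and −5.54 (edgeR adjusted p from 3.86e-08 to 5.01e-08). In sclera with choroid against retina, COL8A2 (log2 7.48), gpa33a (7.62), irf2b (5.47) and lsr (8.11) were higher. CELSR3 (−8.19), slc12a5b (−7.32), YWHAG (−5.42) and GPR27 (−5.44) were lower, all at adjusted p of 4.09e-08 to 4.15e-08. Against RPE, sclera with choroid had more spint1b (log2 4.14), gpa33a (3.95), MYH9 (ENSDARG00000063295; 3.70) and lsr (4.00). It had less GPR143 (−4.48), TYRP1 (−5.05), SLC45A2 (−5.11) and dhrsx (−3.92), with adjusted p of 3.71e-07 to 7.32e-07. The 3 tissue comparisons called 15737, 16744 and 10528 of 22776 genes. Markers of several cell types occurred in each dissected tissue. Corneal and surface epithelium genes summed to 127631 ± 12172 TPM in wild-type sclera with choroid, and fibroblast matrix genes to 22945 ± 1499 TPM (SD, n = 3). Melanosome genes summed to 12556 ± 1211 TPM in wild-type RPE and 371 ± 28.7 in sclera with choroid. Rod genes summed to 59283 ± 4289 TPM in retina, and to 2948, 5092 and 17098 TPM in the 3 wild-type RPE libraries.

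The LRP2 transcript (ENSDARG00000102506) was present in every library of both genotypes. Whole eyes had 2967, 2329 and 2035 counts in wild type and 2606, 1296 and 2334 in mutants, which is 101 ± 15.9 against 84.1 ± 24.4 CPM (log2 −0.26, SE 0.24, adjusted p = 0.711). RPE had 2579, 2105 and 2221 counts in wild type and 1185, 2349 and 2216 in mutants (log2 −0.36, SE 0.25, adjusted p = 0.528). Retina had 3777, 3861 and 3082 counts in wild type and 2731, 3029 and 2583 in mutants, and the level fell from 173 ± 6.5 to 126 ± 7.39 CPM (log2 −0.46, SE 0.08, adjusted p = 0.0046). Sclera with choroid had 130, 234 and 118 counts in wild type and 184, 143 and 168 in mutants (log2 0.01, SE 0.31, adjusted p = 0.989). The second copy, lrp2b, was near 1 CPM in whole eyes and retina, with log2 changes of −0.51 in whole eyes (adjusted p = 0.579) and 0.09 in retina (adjusted p = 0.894). It had at most 4 counts per library in RPE and in sclera with choroid. The labels used here do not give the kind of mutation, so the count over the whole gene does not check the genotype labels.

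**Figure D1:**
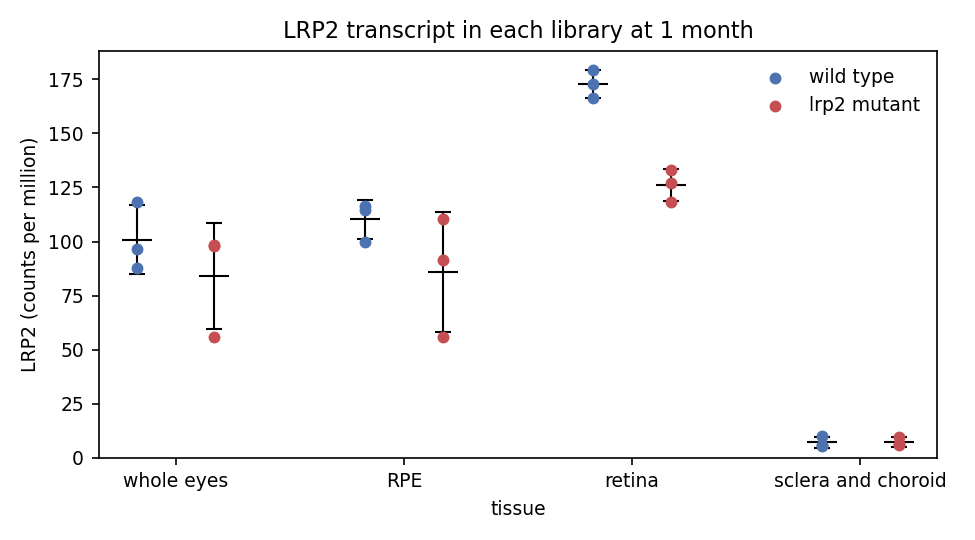
LRP2 in CPM (y axis, linear, TMM-scaled within each tissue) in each library of wild type (blue) and lrp2 mutants (red) at 1 month, by tissue. Points are libraries, black bars give mean ± SD of 3 libraries, and of the 4 tissues only retina passed an adjusted p of 0.05, with means of 126 CPM in mutants and 173 CPM in wild type.

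Whole eyes of lrp2 mutants were set against those of wild type to see how the eye as a unit differed. Sample titles name the wild-type libraries of 1 month ZDR, and genotype and family are not separated in the labels. Effects of lrp2 and of other alleles thus cannot be told apart here or in the tissues below. Of 21411 genes tested, 80 rose and 120 fell. The largest rises included SERPINE3, a member of the serine protease inhibitor family, from 3.86 ± 0.16 to 51.7 ± 10.5 CPM (log2 3.74, SE 0.19, adjusted p = 0.00133). The level of myrfl rose from 0.808 ± 1.02 to 17.9 ± 1.66 CPM (log2 4.48, SE 0.70, adjusted p = 0.045). CFAP20DC (log2 3.01), plekhf1 (2.24), OLFM2 (ENSDARG00000102825; 1.90), fkbp15a (1.87) and itgae.1 (1.82) also rose. The largest falls included CCDC39, which is needed for the dynein arms of motile cilia, from 16.6 ± 5.65 to 0.399 ± 0.266 CPM (log2 −5.38, SE 0.45, adjusted p = 0.00827). The photoreceptor guanylate cyclase activator guca1d fell from 27.9 ± 9.29 to 2.21 ± 0.548 CPM (log2 −3.66, SE 0.31, adjusted p = 0.00827). A serine protease gene known for its part in eye size, prss56, fell from 5.94 ± 1.43 to 0.703 ± 0.372 CPM (log2 −3.06, SE 0.39, adjusted p = 0.0223). The crystallin crygm2d5 (log2 −3.08), mucms1 (−5.11), nlrc11 (−4.56), cyld2 (−3.43) and the Pim-related kinase gene pimr131 (−3.24) fell as well.

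Among the photoreceptor lists of whole eyes, 5 of 32 rod genes and 11 of 43 cone genes had positive log2 changes, with medians of −0.25 (camera adjusted p = 7.13e-05) and −0.26 (8.73e-06). By gene, 1 rod gene rose and none fell over all genes tested (1 and 3 adjusted over the list alone), while 3 cone genes fell (8 adjusted over the list alone). GUCA1A (ENSDARG00000101567), another cyclase activator, was the rod gene that rose, from 220 ± 22.8 to 551 ± 75.6 CPM (log2 1.33, SE 0.15, adjusted p = 0.0145). The cyclase gene gucy2d fell from 321 ± 26.4 to 136 ± 16.8 CPM (log2 −1.24, adjusted p = 0.0138), and the cone channel gene CNGA3 (ENSDARG00000012297) fell as well (log2 −1.89, adjusted p = 0.0467). The lens list, which held 26.0% of all TPM in wild type and 24.1% in mutants, had 7 of 58 positive members (median −0.23, 7.28e-07), with 1 member called lower (3 adjusted over the list alone). Bipolar genes had a median of −0.13 (0.0474) and red blood cell genes −0.29 (0.0107), where the blood transcription factor klf1 rose (log2 1.12). Medians were negative for cholesterol synthesis −0.16 (0.0342), ribosomal proteins −0.08 (0.0143; 0.01 on the log2 TPM scale, where that of all genes was 0.08) and for immediate early genes −0.37 (0.0122; klf2a fell, log2 −2.05). Clock genes had a median of −0.18 (0.0149), with 4 of 38 called lower and 4 higher and 10 lower adjusted over the list alone.

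Lists that lay higher than other genes in mutant whole eyes were melanin and melanosome (19 of 23 positive, median 0.51, 5.46e-07; 0 called, 10 higher adjusted over the list alone) and RPE and visual cycle (21 of 30, 0.16, 0.0149; 1 and 5 higher). Melanosome genes summed to 810 ± 70.8 TPM in mutants and 425 ± 101 in wild type. Matrix lists were higher too: scleral and corneal fibroblast matrix (39 of 47, median 0.51, 8.73e-06), cartilage (24 of 30, 0.53, 0.0143) and matrix metalloproteases (21 of 26, 0.31, 0.00032). FN1 (ENSDARG00000006526), fibronectin, rose from 63.7 ± 3.6 to 127 ± 24.3 CPM (log2 1.00, adjusted p = 0.0381), and COL8A2 (log2 0.82) and the cartilage gene MATN4 (1.18) rose. Skeletal muscle genes had 48 of 51 positive members (median 0.69, 0.0233; 0 called), macrophages and microglia 25 of 29 (0.40, 2.74e-07; 0 called, 9 adjusted over the list alone). Inflammation genes had 24 of 29 positive members (0.49, 7.28e-07; 2 called, 9 adjusted over the list alone), where complement c4b (log2 2.43) and the chemokine cxcl18b (1.51) rose. Lysosome genes had a median of 0.13 (0.00696). BMP ligands and regulators had 31 of 38 positive members (median 0.22, 0.000833), BMP response genes 18 of 25 (0.18, 0.0291). Hedgehog genes had 17 of 26 (0.12, 0.0497) and Wnt genes a median of 0.16 (0.0158), where DKK3 rose (log2 1.28). No single BMP or hedgehog gene was called. All 22 of these list calls were lost with an estimated correlation (adjusted p from 0.629 to 0.908 with an estimated correlation), and other splits of the same 6 libraries called up to 19 lists. Corneal epithelium was not called (median −0.03, 0.579), nor were Müller glia (median 0.09 but mean −0.03, 0.854), amacrine and horizontal cells (0.0829), ganglion cells (0.124), iridophores (0.067) or the LDL receptor family (0.854; 1 of 26 members fell). Median, mean and camera direction also differed in sign for Notch, bone, retinoic acid, growth candidate, glycolysis and hypoxia genes, none of them called.

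The whole-eye count depended on single libraries. It was 1 without mutant replicate 3, 24 without wild-type replicate 2, 31 without mutant replicate 2, 86 without wild-type replicate 3, 96 without wild-type replicate 1 and 359 without mutant replicate 1. DESeq2 called 1034 genes, all 200 of the edgeR calls among them, and 20.4% of genes had no overlap between the groups, where chance gives 10%.

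The RPE was compared because the series title places LRP2 processing there. Of 21064 genes, 121 rose and 168 fell in mutants. Coagulation factor F10 rose from 16.5 ± 3.43 to 202 ± 37.4 CPM (log2 3.62, SE 0.23, adjusted p = 0.00624). The dopamine receptor gene DRD3 rose from 0.321 ± 0.042 to 8.70 ± 0.666 CPM (log2 4.74, SE 0.25, adjusted p = 0.00484), and complement c4b rose from 3.57 ± 0.769 to 84.5 ± 66.5 CPM (log2 4.57, SE 0.69, adjusted p = 0.0423). The claudin cldn26 was at 6.27 ± 0.497 CPM in mutants and had 2 counts in all wild-type RPE, a ratio of 197 (95% interval 54.2 to 1630, adjusted p = 0.00726). PKHD1L1 (ENSDARG00000040004; log2 4.32), spef2 (3.76), igldcp (3.74) and herc56.4 (3.48) rose. The NLR family gene nlrc11 fell from 66.8 ± 16.5 to 0.332 ± 0.044 CPM (log2 −7.63, SE 0.28, adjusted p = 0.00165). The sulfotransferase genes sult3st3 and sult3st2, at 10.7 ± 5.52 and 6.90 ± 3.92 CPM in wild type, had 0 counts in mutants, which is at least 231-fold and 149-fold lower (adjusted p = 0.0306 and 0.0365), and sult1st7 fell (log2 −6.11). BCO2 (ENSDARG00000041715), which cleaves carotenoids, fell from 14.7 ± 3.84 to 0.882 ± 0.432 CPM (log2 −4.04, SE 0.43, adjusted p = 0.0223), as did gfus.3 (log2 −7.69), CAPN3 (ENSDARG00000041864; −4.76) and atp1a1a.3 (−4.58).

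Red blood cell genes lay lower in mutant RPE, with 17 of 18 members negative (median −1.06, camera adjusted p = 9.54e-08). The globin hbaa1 fell from 6594 ± 541 to 1250 ± 385 CPM (log2 −2.40, SE 0.26, adjusted p = 0.0236) and CREG1 fell (log2 −1.45), 2 members by all genes and 9 adjusted over the list alone. Their summed level was 4533 ± 1296 TPM against 18883 ± 2080 in wild type. Skeletal muscle genes lay lower (44 of 48 negative, median −1.76, 2.18e-06; 0 called, 2 higher and 23 lower adjusted over the list alone), although their summed level was 3627 ± 590 TPM against 3031 ± 791. Lens genes also lay lower (43 of 45 negative, median −0.86, 2.52e-08; 0 called), as did iridophore genes (median −0.39, 0.000454) and glycolysis (−0.30, 0.00807; PFKP (ENSDARG00000028000) fell, log2 −0.78). Oxidative phosphorylation had a median of −0.14 (0.0136), which was 0.05 on the log2 TPM scale, where that of all genes was 0.15. Its members COX6A1 (ENSDARG00000054588; log2 −2.20), cox8b (−1.65) and cox7a1 (−1.58) fell. Inflammation genes lay higher (28 of 31 positive, median 0.83, 5.72e-06; 1 called, 12 adjusted over the list alone). So did macrophages (27 of 29, 0.34, 0.000454), proliferation (44 of 45, 0.56, 6.6e-05; 0 called) and matrix metalloproteases (20 of 25, 0.38, 0.00718). Among the last, ADAMTS1 rose from 50.1 ± 13.0 to 237 ± 37.3 CPM (log2 2.24, SE 0.23, adjusted p = 0.021). All 10 list calls were lost with an estimated correlation (adjusted p of 0.945 or 0.959 with an estimated correlation), and other splits of the same 6 libraries called up to 22 lists.

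The RPE's own lists were not called: RPE and visual cycle had 14 of 32 positive members (median −0.10, camera adjusted p = 0.301; 0.03 on the log2 TPM scale) and melanin 8 of 23 (−0.06, 0.184; 1 called lower). RPE and visual cycle genes summed to 8476 to 12878 TPM in the 3 mutant libraries and 14140.2 to 24578 in wild type. Of its abundant members, picked after their values were seen, RGR (log2 −2.17, SE 0.52, edgeR adjusted p = 0.107) and rlbp1b (−1.44, SE 0.38, adjusted p = 0.135) lay lower in each mutant library than in each wild-type one without passing the test. Genes of neighbouring tissues varied between libraries. Corneal epithelium genes summed to 35877, 11784 and 4270 TPM in the 3 mutant RPE libraries against 13493 to 15740 in wild type, with a median and a mean above 0 and a camera test below (0.40, 0.45, 0.305). Rod genes (median −0.40, 0.935), cone genes (0.51, 0.292), cartilage (0.44, 0.14) and fibroblast matrix (median 0.01, mean −0.18, 0.868) were not called. Secretases had 15 of 20 positive members (0.15, 0.0662), BMP ligands 25 of 40 (0.12, 0.362; 1 called higher) and BMP response genes 10 of 27 (−0.11, 0.162), with 0 BMP response genes called. Ribosomal proteins had a median of −0.08 (0.0539). Median, mean and camera direction also differed in sign for LDL receptor family, Müller glia, myelin and ER stress genes, none of them called.

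The RPE count was 4 without wild-type replicate 11, 42 without 12, 13 without 13, 22 without mutant replicate 12, 27 without 13 and 549 without mutant replicate 21, and limma on log2 TPM called 246 higher and 169 lower. Mutant replicate 21 was hardly closer to its own group (median correlation 0.901) than to wild type (0.899). Every other RPE library had at least 0.924 to its own group. DESeq2 called 1819, including all 289, the fit of all 24 libraries 1994, and 23.8% of genes had groups without overlap, where chance gives 10%.

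In retina 1632 genes were higher and 2277 lower of 20065 tested, and limma on log2 TPM called 1564 higher and 1469 lower. The edgeR count was the largest of the 4 tissues when each was fitted alone, but not in the fit of all 24 libraries, with 1745 in retina, 1994 in RPE and 2250 in sclera with choroid. The named genes with the largest rises were nuggc.2, from 0.307 ± 0.223 to 9.14 ± 0.293 CPM (log2 4.94, SE 0.33, adjusted p = 2.96e-05), F10 (log2 4.29, SE 0.39, adjusted p = 0.000252) and the integrin gene ITGA10, from 1.84 ± 1.71 to 33.6 ± 5.76 CPM (log2 4.14). They were followed by nuggc.1 (4.11), adgre9 (4.04), hbegfa (3.77) and mybpc2b (3.42). Falls were led by pimr131, from 10.2 ± 4.81 to 0.071 ± 0.066 CPM (log2 −6.98, SE 0.69, adjusted p = 0.0012), KCNK5 (ENSDARG00000023587; −6.65), slc37a4bl (−5.32), nlrc11, from 13.8 ± 0.161 to 0.356 ± 0.14 CPM (−5.29, SE 0.22, adjusted p = 1.27e-06), sim1b (−4.92), SCG5 (−3.38), znf977 (−3.37) and ABCA12 (−3.2).

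Rod genes fell as a group in mutant retina: 25 of 32 members had negative changes (median −0.38, camera adjusted p = 7.24e-06), and 21 fell and 2 rose over all genes tested (22 and 2 adjusted over the list alone). GRK1, the rhodopsin kinase, fell from 823 ± 20.9 to 558 ± 16.4 CPM (log2 −0.56, SE 0.07, adjusted p = 0.000842) and RGS9 (ENSDARG00000045156), which speeds the shut-off of transducin, from 128 ± 9.01 to 73.9 ± 7.59 CPM (log2 −0.79, SE 0.10, adjusted p = 0.000799). Copies of the rod channel gene CNGA1 fell by 0.55 and 0.60 on the log2 scale. The list gave an adjusted p of 0.892 with an estimated correlation and 0.0388 by fry. Cone genes went both ways, 9 higher and 19 lower of 43 (11 and 19 adjusted over the list alone; camera 0.116). The green opsin opn1mw3 rose from 832 ± 123 to 1469 ± 71.3 CPM (log2 0.82, SE 0.11, adjusted p = 0.0012). In contrast gucy2d fell from 519 ± 105 to 218 ± 28.8 CPM (log2 −1.25, SE 0.16, adjusted p = 0.00174) and PDE6H fell (−0.59). Summed rod TPM were 50484 ± 2342 against 59283 ± 4289, and summed cone TPM 105910 ± 9166 against 97804 ± 9077.

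Lists of other retinal cells were not called (camera adjusted p of 0.783 for Müller glia, 0.187 for bipolar, 0.0507 for amacrine and horizontal, and 0.659 for ganglion cells). Of 26 Müller glia genes, 5 rose and 6 fell. GFAP, the intermediate filament of glia, fell from 64.5 ± 13.4 to 26.6 ± 1.93 CPM (log2 −1.28, SE 0.14, adjusted p = 0.000837), and the glutamate transporter SLC1A2 (−1.44) and carbonic anhydrase cahz (−1.33) fell, while CAV1 rose (1.12). Bipolar genes had 4 of 24 lower and none higher, with cabp5a (−1.23), cabp2a (−0.79), PRKCA (−0.58) and TRPM1 (−0.31). Amacrine and horizontal cell genes had 9 lower and 1 higher of 34, with ONECUT2 (−1.2) and GAD1 (−0.40). Ganglion cell genes had 3 and 3 of 28, with NEFL (−0.81), nefma (−0.66), CHRNA6 (−0.43) and rbpms (1.24). Vascular genes had 10 higher and 3 lower of 30 (median 0.47, camera 0.0228, adjusted p = 0.892 with an estimated correlation), with SOX7 (1.28), clec14a (1.23), TIE1 (1.2) and stab2 (−2.28). Ribosomal proteins had 71 of 73 positive members and 0 called (median 0.15, 2.56e-05, adjusted p = 0.892 with an estimated correlation). Other splits of the same 6 libraries called up to 14 lists.

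Genes of the pathways in the title were tested in the retina as well. Of all 20065 genes tested there 3909 were called, and counts of called members in retinal lists, above and below, are to be read against that share. The count of the BMP ligands and regulators lay near it. Of 36 BMP ligands and regulators, 3 rose and 4 fell (0.68). Among them FST (ENSDARG00000052846), follistatin, an extracellular binder of activins, rose from 13.9 ± 1.98 to 83.5 ± 42.3 CPM (log2 2.59, SE 0.47, adjusted p = 0.0251). BMPR1A (ENSDARG00000019728) rose (0.51), and BMP2 (−1.06) and GDF10 (−1.25) fell. BMP response genes had 2 higher of 21 (0.195), hedgehog genes 1 lower of 25 (0.796), and Notch genes 2 lower of 22 (0.796). Wnt genes had 2 higher, with DKK3 at 2.21, and 1 lower, with NKD1 at −1.16, of 20 (0.796). Of 23 TGF-beta genes 4 rose and 3 fell (0.796), with TGFB3 up from 98.1 ± 5.15 to 177 ± 10.4 CPM (log2 0.85, SE 0.08, adjusted p = 0.000252) and LTBP1 down (−0.64). Among 27 LDL receptor family genes, DAB2 (ENSDARG00000053091) rose (0.64) and dab2 (ENSDARG00000031761; −0.51), LRP3 (−0.60) and lrp11 (−0.34) fell. Among 21 processing proteases, FURIN (ENSDARG00000062909) rose (0.36) and FURIN (ENSDARG00000070971; −0.52), BMP1 (−0.90) and ADAM17 (ENSDARG00000093093; −0.84) fell. Of 30 candidates for ocular growth and refraction, 1 rose and 6 fell (camera 0.267, fry 0.0388). Of these prss56 fell from 12.4 ± 3.64 to 1.66 ± 0.557 CPM (log2 −2.90, SE 0.30, adjusted p = 0.000729). The retinoid carrier gene rbp3 fell from 2829 ± 369 to 1545 ± 315 CPM (log2 −0.87, SE 0.16, adjusted p = 0.00936) and RASGRF1 fell (−0.65), while the dopamine receptor gene DRD2 (ENSDARG00000011091) rose (0.90).

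The remaining retinal lists were not called by camera. In counts higher and lower, they were inflammation 5 and 1 of 18 (0.0507; mhc1uba rose from 4.31 ± 0.571 to 39.4 ± 2.69 CPM, log2 3.2, adjusted p = 8.07e-07), macrophages 3 and 2 of 25 and neutrophils 0 and 0 of 9 (0.328). Next came bone 2 and 5 of 12, cholesterol synthesis 0 and 6 of 27 (0.0533; LSS −0.81), and lysosome 5 and 0 of 39 (MCOLN1 0.97). Others were clock 7 and 3 of 38, retinoic acid 2 and 4 of 27 (BCO2 (ENSDARG00000055722) −1.84), hypoxia 7 and 8 of 31, and glycolysis 3 and 7 of 30 (SLC2A1 −0.96). They further held oxidative phosphorylation 4 and 2 of 60, heat shock 5 and 2 of 31 (hsp90aa1.1 −2.87), and ER stress 5 and 4 of 28 (ATF3 1.14). There were also immediate early genes 4 and 1 of 27, metalloproteases 4 and 3 of 24 (ADAMTS9 0.98), intraocular pressure genes 3 and 2 of 15 (MYOC −2.34), iridophores 2 and 1 of 16, myelin 1 and 1 of 13, and proliferation 1 and 1 of 45. Markers of other tissues were RPE 3 and 1 of 28 (0.314), melanin 2 and 1 of 20 (0.268; GPR143 1.2), muscle 4 and 5 of 32 (0.916), red blood 4 and 4 of 14 (0.916), corneal epithelium 2 and 4 of 27 (0.195), fibroblast matrix 3 and 2 of 40 (0.959; COL12A1 1.94) and cartilage 0 and 3 of 27 (0.997). Lens genes had a median of −5.04 over 50 members with 1 called higher (0.342), because 1 library stood apart: they summed to 59059 TPM in wild-type retina replicate 12, against 380 and 448 TPM in the other wild-type libraries and 505 to 572 TPM in mutants. Median, mean and camera direction differed in sign for hedgehog, TGF-beta, macrophage and immediate early genes. The retina count was 3197 without that library. It was 2359 without wild-type replicate 11 and 2020 without mutant replicate 13. Groups had no overlap for 39.6% of genes, where chance gives 10%.

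In sclera with choroid, the wall of the eye, 595 genes rose and 809 fell of 21159. DRD3 rose from 0.21 ± 0.042 to 8.78 ± 0.933 CPM (log2 5.34, SE 0.25, adjusted p = 0.000332). The adhesion receptor gene adgrf11 had 3 counts in wild type and 383 in mutants, a ratio of 120 (95% interval 40.9 to 587, adjusted p = 0.00757). The gamma crystallin crygm2d5 rose from 0.134 ± 0.071 to 5.87 ± 1.34 CPM (log2 5.38, SE 0.41, adjusted p = 0.00136), with crygm2d20 (4.27), crygm2d4 (4.1) and crygm2d17 (3.95), and lipib (3.86) and xkr8.4 (3.54) rose. Other crystallins fell: crygm3 and crygm2a, at 5.61 ± 1.42 and 5.48 ± 0.712 CPM in wild type, had 0 counts in mutants, at least 132-fold and 129-fold lower. Likewise crygm1 and CRYBB2 had 1 count each, ratios of 459 (95% interval 81.9 to 18200) and 441 (78.7 to 17500), and crygm2e fell (−5.30). In all, 13 lens genes rose and 12 fell of 46 (18 and 16 adjusted over the list alone). The median was positive (0.16), the mean negative (−1.0) and the camera adjusted p 0.725. The lens sum was 379 ± 21.8 TPM against 299 ± 67.2. The fucose synthesis gene gfus.3 fell from 214 ± 75.6 to 0.195 ± 0.214 CPM (log2 −10.22, SE 0.69, adjusted p = 0.00136). The antigen presentation genes mhc2dga, from 27.7 ± 14.4 CPM to 0 counts (at least 659-fold), and mhc2dgb (−8.50) fell, and so did mucms1 (−8.53). Reads of these paralogous families cannot be assigned with certainty.

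Vascular genes lay lower in mutant sclera with choroid (28 of 31 negative, median −0.58, camera adjusted p = 9.11e-06; 5 called, 13 adjusted over the list alone). KDR, a receptor for vascular endothelial growth factor, fell from 64.9 ± 22.3 to 23.0 ± 1.11 CPM (log2 −1.50, SE 0.25, adjusted p = 0.0204), with she (−1.40), MRC1 (−1.27) and stab2 (−1.24). Macrophages (median −0.53, 0.00126; 3 called lower, 4 adjusted over the list alone) and neutrophils (−0.98, 0.00518; 3 and 4) were lower, with MPEG1 (ENSDARG00000078569; −6.45), lyz (−2.03), il6r (−2.10), CEBPA (−1.23) and cd74a (−0.80). Bone genes (15 of 16 negative, −0.91, 0.000936; 0 called), corneal epithelium (28 of 34 negative, −0.35, 0.00518; cyt1l rose, 1.69) and muscle (42 of 51 negative, 0.00518; 7 called lower, among them myhz1.3 at −5.21 and myhz1.2 at −4.01) were lower. ER stress genes (−0.25, 0.00126; TRIB3 −1.28), glycolysis (−0.20, 0.0378) and ribosomal proteins (−0.15, 2.72e-06; 0 called) had negative medians. The last was 0.02 on the log2 TPM scale, where the median of all genes was 0.14. Higher lists were proliferation (39 of 46 positive, 0.27, 0.00126; MCM6 4.36) and Wnt genes (16 of 21, 0.33, 0.0114; SFRP5 0.86, WNT11 0.75). Another was BMP ligands and regulators (32 of 40, 0.14, 0.0402), where FST (0.76, adjusted p = 0.0291) and GDF5 (1.14, adjusted p = 0.0425) rose. All 12 list calls were lost with an estimated correlation (adjusted p = 0.835 with an estimated correlation), and other splits of the same 6 libraries called up to 21 lists.

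Further called genes of sclera with choroid were the growth factor IGF1, up from 3.89 ± 1.19 to 11.7 ± 2.54 CPM (log2 1.58, SE 0.26, adjusted p = 0.0203), igf2a (0.56) and gcga (−2.32) among the growth candidates. MYOC fell from 28.2 ± 3.79 to 9.52 ± 1.53 CPM (log2 −1.57, SE 0.16, adjusted p = 0.00437) and angptl7 (−1.32) fell among the intraocular pressure genes, 1 higher and 2 lower of 18. The gene mhc1uba rose from 225 ± 28.9 to 754 ± 210 CPM (log2 1.75, SE 0.22, adjusted p = 0.0104), among 4 higher inflammation genes of 32. THBS4 (−1.32), BGN (ENSDARG00000002945; −0.56) and COL14A1 (−0.47) fell and PRRX1 (ENSDARG00000042027) rose (0.70) among 47 fibroblast matrix genes (median −0.18, 0.122). mmp23bb (−0.98) and TIMP2 (−0.61) fell and TIMP4 rose (0.77). Hypoxia had 4 lower and 1 higher of 30, with igfbp1b (−2.14) and EPAS1 (−1.61). Lists of neighbouring tissues were not called: rods (26 of 29 positive, 0.83, 0.0817; 1057 ± 438 against 693 ± 219 TPM), cones (32 of 39, 0.96, 0.0823), melanin (19 of 23, 0.51, 0.0564), RPE (0.06, 0.432), cartilage (median 0.17 but camera below, 0.45) and red blood (−0.15, 0.191). BMP response genes had 1 higher of 25 (0.239), hedgehog genes 1 lower of 26 (0.191), and TGF-beta genes none of 23 (0.806). Median, mean and camera direction also differed in sign for secretase, hedgehog, Notch, Müller glia, ganglion cell and intraocular pressure genes, none of them called.

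The sclera and choroid count was 647 without wild-type replicate 11, 882 without wild-type 12, 764 without mutant 11, 355 without mutant 12 and 434 without mutant 13. It was 3020 with DESeq2, 2250 in the fit of all 24 libraries and, on log2 TPM with limma, 1213 higher and 615 lower. Groups had no overlap for 32.4% of genes, where chance gives 10%.

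Some circadian genes were called in each tissue of the mutants. The period gene PER1 (ENSDARG00000056885) fell from 19.6 ± 3.72 to 4.29 ± 0.81 CPM in whole eyes (log2 −2.19, SE 0.21, adjusted p = 0.00931) and from 23.2 ± 9.08 to 2.68 ± 1.48 CPM in sclera with choroid (log2 −3.13, SE 0.53, adjusted p = 0.0235), with −2.88 in RPE (adjusted p = 0.0519) and −1.52 in retina (0.0867). PER3 fell in retina, from 255 ± 63.0 to 72.9 ± 9.31 CPM (log2 −1.80, SE 0.18, adjusted p = 0.00101), and in RPE (−1.58, adjusted p = 0.042). The activator bmal2 rose in RPE (1.93, adjusted p = 0.034), retina (1.2, 0.0114) and sclera with choroid (1.3, 0.0461), and CLOCK (ENSDARG00000011703) rose in RPE from 12.5 ± 2.36 to 33.5 ± 2.44 CPM (log2 1.42, SE 0.17, adjusted p = 0.027). The output factors dbpb (−1.68 in RPE, −1.88 in sclera with choroid), tefa (−1.13 in RPE, −0.88 in sclera with choroid) and tefb (−1.25 in retina, −0.93 in sclera with choroid) fell. The list of 38 had 3 higher and 3 lower in RPE (11 and 16 adjusted over the list alone, camera 0.409), 7 and 3 in retina (8 and 4, 0.796), and 1 and 7 in sclera with choroid (9 and 15, 0.282). Over all genes 289 of 21064 were called in RPE, 3909 of 20065 in retina and 1404 of 21159 in sclera with choroid. The time of collection is not given in the labels used here.

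**Figure D2:**
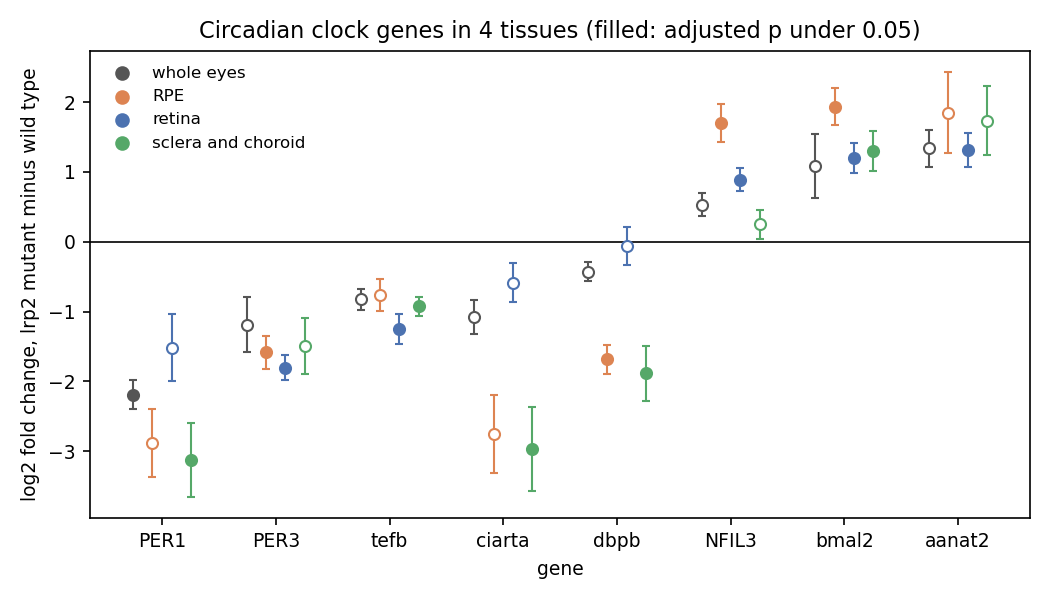
Log2 fold changes (y axis, lrp2 mutant minus wild type, 3 libraries each) of 8 circadian genes (x axis) in whole eyes, RPE, retina, and sclera with choroid, with error bars of 1 standard error. Filled points passed an adjusted p of 0.05, and PER1, PER3, tefb and ciarta lay below 0 and bmal2 and aanat2 above 0 in all 4 tissues. The 8 genes were picked by hand from the list of 38, so they do not stand for it. Of the 4 tissues, camera called that list only in whole eyes, at the preset correlation.

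Genes called in the mutant tissues overlapped by more than independent lists would give. Retina and sclera with choroid shared 213 higher and 226 lower genes, where 43.0 and 64.6 would be shared by independent lists (two-sided Fisher's exact test, adjusted p = 2.98e-95 and 2.45e-69), and 33 went opposite ways. RPE shared 47 higher and 66 lower with sclera with choroid (3.32 and 5.80 for independent lists) and 52 and 60 with retina (8.45 and 15.0, with 11 opposite). Whole eyes shared 12 and 15 with RPE, 46 and 78 with retina, and 26 and 41 with sclera with choroid (4 opposite). DRD3, F10, nlrc11, gfus.3, mucms1 and pimr131 were among the named genes called in more than 1 tissue. Of the genes called and changed more than 4-fold in the same direction in at least 2 dissected tissues there were 134, of which 61 were higher and 73 lower, and 94 had only a clone name or an identifier. The lrp2 effect itself differed between tissues for 459 genes in RPE against retina, 583 in sclera with choroid against retina and 163 in sclera with choroid against RPE (interaction contrasts of edgeR). The last count was 43, 28 of them among the 163, when only the 12 libraries of both tissues were fitted. NENF, a secreted neurotrophic factor, had a log2 change in mutants of −4.24 in sclera with choroid and 1.41 in retina. The difference was −5.66 (SE 0.36, adjusted p = 5.51e-08). For UBA6, a ubiquitin-activating enzyme, the log2 change in mutants was 2.34 in RPE and 0.28 in retina, a difference of 2.06 (SE 0.20, adjusted p = 1.81e-05).

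Larval eyes with the bmp4 transgene were set against those of their own controls at 5 days. BMP4 had 6494, 6736 and 5555 counts in transgenic and 171, 179 and 204 in control libraries, and rose from 7.48 ± 0.845 to 256 ± 17.0 CPM (log2 5.10, SE 0.13, adjusted p = 6.22e-06). Of 21035 genes, 17 rose and 5 fell. The antagonist gene nog2, a noggin, rose from 1.74 ± 0.139 to 18.5 ± 2.29 CPM (log2 3.40, SE 0.16, adjusted p = 0.000367). The BMP transducer smad9 rose from 5.89 ± 1.33 to 45.7 ± 4.03 CPM (log2 2.95, SE 0.17, adjusted p = 0.000921). The homeobox gene msx2b rose from 2.70 ± 0.461 to 14.6 ± 1.85 CPM (log2 2.44, SE 0.18, adjusted p = 0.00376) and the inhibitory SMAD6 (ENSDARG00000031763) from 8.33 ± 0.959 to 33.1 ± 2.97 CPM (log2 1.99, SE 0.13, adjusted p = 0.00163). NOG (ENSDARG00000058819; log2 2.99), atoh8 (2.32), dkk2 (2.09), C1QTNF12 (2.07), PRRX1 (ENSDARG00000033971; 1.23), the second SMAD6 (ENSDARG00000053209; 0.97) and BMPR1A (ENSDARG00000105045; 0.85) also rose. CYP27C1, which converts vitamin A1 to A2, fell from 25.0 ± 2.48 to 8.14 ± 0.644 CPM (log2 −1.62, SE 0.12, adjusted p = 0.00425), and ALDH1A3, a synthetic enzyme of retinoic acid, from 15.7 ± 0.301 to 6.17 ± 0.104 CPM (log2 −1.35, SE 0.11, adjusted p = 0.00581), with CLDN11 (ENSDARG00000020031; −1.28), EMX2 (−1.07) and FHL3 (ENSDARG00000034643; −0.95).

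BMP response genes rose as a list (23 of 26 positive, median 0.59, camera adjusted p = 8.79e-33; 6 called higher, 16 adjusted over the list alone; 0.0141 by fry; adjusted p = 0.247 with an estimated correlation). BMP ligands and regulators had 5 called higher of 39 (10 higher and 6 lower adjusted over the list alone; median 0.20, 1.75e-05; 0.0178 by fry; adjusted p = 0.503 with an estimated correlation). Lower lists were corneal epithelium (27 of 32 negative, median −0.28, 8.07e-09, adjusted p = 0.535 with an estimated correlation). So were fibroblast matrix (−0.15, 0.0134; 0.775), lens (−0.14, 0.0346; 0.901), inflammation (−0.12, 0.0299; 0.503), ribosomal proteins (−0.15, 9.49e-14; 0.901) and oxidative phosphorylation (−0.10, 1.75e-05; 0.901), where the second value in brackets is the adjusted p with an estimated correlation. Rods (0.692), cones (0.799), RPE (0.352), melanin (0.152), cartilage (0.112), muscle (0.955), red blood (0.815), hedgehog (0.74) and retinoic acid genes (0.799) were not called. The other splits that part all 3 pairs of libraries called 6, 8 and 7 lists against 8 in the real one, and splits that part 1 pair called up to 20. With the replicate number as a block, the same 22 genes were called among 609 (333 higher, 276 lower), and secretases (0.0142), bone (0.0145), proliferation (0.0109) and lysosome (0.049) joined the lists under 0.05. The unblocked count was 6, 9 and 8 without bmp4 replicate 11, 12 and 13, and 8, 7 and 12 without the controls of those numbers. DESeq2 called 64 higher and 41 lower, and limma on log2 TPM 14.

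**Figure D3:**
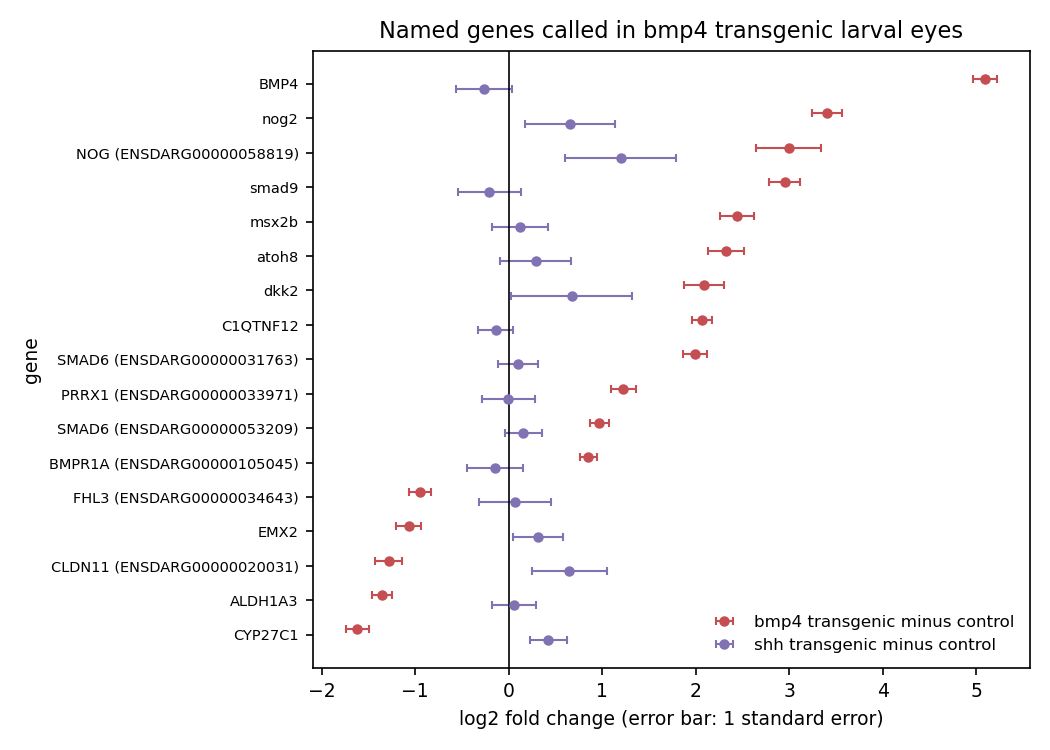
Log2 fold changes (x axis, transgenic minus control, 3 libraries each, error bars of 1 standard error) of the named genes called in bmp4 larval eyes (y axis), in the bmp4 line (red) and the shh line (purple). BMP4 itself lay at 5.10 in the bmp4 line and at −0.26 in the shh line, where none of these genes was called.

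Larval eyes with the shha transgene had SHH (ENSDARG00000068567) at 1208, 3426 and 786 counts against 184, 452 and 179 in controls, which is 80.2 ± 53.2 against 10.0 ± 5.99 CPM (log2 3.00, SE 0.62, adjusted p = 0.90). The other gene of that symbol, SHH (ENSDARG00000038867), was at 5.58 ± 1.76 against 4.00 ± 2.13 CPM. No gene of 20812 was called by edgeR, where 113 had an unadjusted p under 0.05 and 1041 would by chance if the libraries were not paired. DESeq2 called 2, SHH (ENSDARG00000068567) and si:dkey-221l4.9, and limma on log2 TPM 0. Among the 5 genes with the smallest p were foxd2 (4.71 ± 1.38 against 1.71 ± 0.315 CPM, log2 1.46), si:dkey-103d23.3 (log2 −2.14), sult3st1 (−2.04) and si:dkey-221l4.9 (1.17 ± 0.39 CPM against 0 counts, at least 30.6-fold), all at an adjusted p of 0.90. Hedgehog targets such as HHIP (log2 0.89, SE 0.26), GLI1 (0.48, SE 0.25) and PTCH1 (0.10, SE 0.66) did not pass, and 14 of 25 members of that list were positive (median 0.04, camera 0.65).

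Camera called 10 lists in the shh set with 0 member genes called, and none held with an estimated correlation (adjusted p = 0.634 with an estimated correlation), while the other splits that part all 3 pairs called 9, 12 and 8 and those that part 1 pair up to 18. Ribosomal proteins (72 of 73 positive, median 0.76, 4.72e-14), oxidative phosphorylation (59 of 59, 0.62, 7.77e-13), and lens (50 of 55, 0.72, 7.44e-09) had positive medians. So had proliferation (40 of 45, 0.32, 5.31e-10), heat shock proteins (30 of 33, 0.31, 0.000117), corneal epithelium (27 of 32, 0.38, 0.00034), RPE (25 of 31, 0.29, 0.00071) and ER stress (20 of 28, 0.25, 0.00648). Medians were negative for TGF-beta (−0.24, 0.0423) and clock genes (−0.16, 0.0423). On the log2 TPM scale, where the median of all genes was −0.27, the medians of RPE, corneal epithelium, proliferation, heat shock and ER stress genes turned negative. Replicate 13 of the transgenic group stood apart, with a median correlation of 0.818 to its own group and 0.817 to the controls, where every other library of the set had at least 0.889. Its ribosomal protein genes summed to 203063 TPM against 127425 to 147058 in the other 5 libraries. Rods (0.335), cones (0.0658), melanin (0.372), muscle (0.0846), red blood (0.517), cartilage (0.0871) and fibroblast matrix (0.325) were not called. With the replicate number as a block 0 genes were called, and cones (0.0365), Müller glia (0.0481), metalloproteases (0.0421), inflammation (0.0106) and immediate early genes (0.0481) joined the lists under 0.05. In fits added after that library was seen to stand apart, leaving out both libraries numbered 13 called 28 genes with the block, among them SHH (ENSDARG00000068567) and si:dkey-221l4.9, and 0 without it. Leaving out only the transgenic one called 21 with the block, among them the same SHH gene.

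The bmp4 effect differed from the shh effect for 5 genes. BMP4 (difference 5.36, SE 0.29, adjusted p = 3.4e-05), smad9 (3.16), C1QTNF12 (2.21) and SMAD6 (ENSDARG00000031763; 1.89) rose more, and CYP27C1 (−2.04, adjusted p = 0.0146) fell more, with bmp4. With the block 2 genes were called, of which only BMP4 was among these 5. The 2 groups of control larvae differed by 4 genes, among them hsp90aa1.1 (log2 2.03) and tnnt2d (1.89), higher in the bmp4 set, and slc22a4 (−4.14). Calls of the bmp4 line without the block overlapped with those of mutant whole eyes or mutant RPE in 0 genes by edgeR. Independent lists would share 0.03 to 0.08 per direction, and by DESeq2 5 and 6 genes were shared. The 609 calls with the block were not compared with those of the mutants. Fold changes without the block had Pearson correlations of −0.008 and −0.013 across genes.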

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

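The differences of effects and their contrasts were fixed before the data were examined, and the splits that swap labels within pairs of larval libraries were the only test in this part chosen after other results were seen. What drew attention here were differences between groups, each tested as the difference itself with an interaction contrast of edgeR.

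The lrp2 effect differed between RPE and retina for 459 genes. The largest positive differences among those named were pimr131 (8.40, SE 0.71, adjusted p = 9.43e-06), pimr136 (5.94), UBA6 (2.06) and fam234a (1.70), and the negative ones ADRB3 (−2.58), DPP7 (−1.82), ACACB (−1.59) and scp2a (−1.29). In retina pimr131 had a log2 change of −6.98 and in RPE 1.41. Reads of pimr family members cannot be assigned with certainty. DPP7, a lysosomal peptidase, had a log2 change of 2.2 in retina and 0.37 in RPE, and the adrenergic receptor gene ADRB3 1.76 and −0.83.

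Between sclera with choroid and retina the effect differed for 583 genes, with pimr131 (7.41), sim1b (5.70), DOCK4 (ENSDARG00000076213; 2.79) and fam234a (1.61) more positive in sclera with choroid, and NENF (−5.66), ADRB3 (−2.73), DPP7 (−1.77) and the metalloprotease gene mmp23bb (−1.44) more negative. NENF was at 1.85 CPM in mutant and 35.3 CPM in wild-type sclera with choroid. Between sclera with choroid and RPE it differed for 163 genes, with cav4a (3.58), gfra1a (2.56), the tendon homeobox gene MKX (2.15) and GDPD1 (1.47) more positive in sclera with choroid, and the chemokine gene ccl19a.1 (−5.57), NENF (−2.35), UBA6 (−2.15) and RPS6KA1 (−1.16) more negative. In mutant RPE ccl19a.1 was at 119 ± 121 CPM, a spread as large as its mean, against 2.99 ± 0.583 CPM in wild type.

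Genotype labels were permuted within each tissue in 40 drawn splits, the real one included. For each of the 3 differences 1 of 40 splits, the real one, gave as many genes, a share of 0.025. That share is the smallest that 40 splits can give. These splits also remove the lrp2 effect that tissues have in common, so they do not set the count against equal effects. They take libraries as independent, but the libraries of a group may be technical. Same-numbered libraries of sclera with choroid and RPE also had correlations of 0.06 to 0.27 in wild type and 0.1 to 0.4 in mutants. The share therefore cannot decide on chance, even with no effect in any tissue. The highest of the other splits gave 164 genes for RPE against retina, 91 for sclera with choroid against retina and 53 for sclera with choroid against RPE. When only the 12 libraries of both tissues were fitted, sclera with choroid against RPE had 43 genes, 28 of them among the 163, and no splits were drawn for that fit.

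The bmp4 effect differed from the shh effect for 5 genes, BMP4 (5.36), smad9 (3.16), C1QTNF12 (2.21), SMAD6 (ENSDARG00000031763; 1.89) and CYP27C1 (−2.04). With the replicate number as a block 2 genes were called, and BMP4 was the only one of these 5 among them. Of 80 drawn splits, which do not keep the pairs of these libraries, 4 gave as many genes, a share of 0.05, and the highest other gave 8. Of the 32 splits that swap labels only within pairs, 5 gave as many genes, with 7 in the highest other, and with the block 2 gave as many, with 2 in the highest other. None of these shares was under 0.05, so chance was not excluded. The drawn splits shuffled the labels of each line apart, and a draw could keep or mirror the bmp4 labels and with them the bmp4 effect. Which draws did so was not recorded, so their share cannot decide on chance. The within-pair shares cannot decide on it either. The other within-pair splits with as many genes, in both fits, kept the bmp4 labels and swapped shh labels in part or in full. The bmp4 effect thus stayed in them. Within-pair splits that swapped a bmp4 pair called 0 genes without the block and at most 1 with it. Expression values of the larval lines were deposited in separate tables.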

How the results depend on the processing

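Fits that left out the shh libraries numbered 13 were chosen after those libraries were seen, and all other alternatives were fixed before. The cause of the changes below was not tested unless a cause is given.

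With DESeq2 the genes called were 1034 in whole eyes, 1819 in RPE, 3020 in sclera with choroid, 105 in the bmp4 line and 2 in the shh line, against 200, 289, 1404, 22 and 0 with edgeR, and in simulations DESeq2 had the higher share of false calls. In the fit of all 24 libraries, which shares 1 estimate of the spread, they were 461 in whole eyes, 1994 in RPE, 1745 in retina and 2250 in sclera with choroid. limma on log2 TPM called 14 in the bmp4 line. Leaving out each library in turn gave 1 to 359 genes in whole eyes, 4 to 549 in RPE, 2020 to 3477 in retina, 355 to 1090 in sclera with choroid, 6 to 12 in the bmp4 line and 0 in the shh line, with fewer samples in each fit. With a replicate block, leaving out both shh libraries numbered 13 called 28 genes and leaving out only the transgenic one 21. The difference between sclera with choroid and RPE had 43 genes when only the 12 libraries of these tissues were fitted, and that between sclera with choroid and retina 872, 493 higher and 379 lower, against 253 and 330. RLE scaling, no filter on low counts and leaving out crystallins and haemoglobins kept each count of the 6 comparisons within 1.5 times. The 3 wild-type tissue comparisons stayed within 1.5 times under every alternative run, at 14670 to 16048, 15902 to 17007 and 9071 to 11259 genes.

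In the lrp2 comparisons the libraries share only a number. Same-numbered libraries had correlations of 0.02 to 0.28 in whole eyes, −0.33 to 0.01 in RPE, −0.07 to 0.01 in retina and −0.16 to 0.00 in sclera with choroid, and not every library correlated best with its own number in any of them. With the replicate block 409 genes were called in whole eyes, 0 in RPE, 3253 in retina and 368 in sclera with choroid, and 21 lists in RPE and 9 in retina. The 0 in RPE says nothing of stability, because only 2 numbers occur in both groups and the blocked fit recovered 0 of the genes changed 2-fold or 4-fold in the simulation. In the paired larval lines the block called 609 genes for bmp4, 0 for shh, and 2 for the difference between the lines, 1 of them among the 5 without the block, and changed no call of a named gene of the bmp4 line. With a block of genotype and number the differences of the lrp2 effect had 330 genes for RPE against retina (229 of the 459), 497 for sclera with choroid against retina (334 of the 583) and 118 for sclera with choroid against RPE (73 of the 163). Same-numbered libraries of these last tissues had correlations of 0.06 to 0.27 in wild type and 0.10 to 0.40 in mutants, each best with its own number. In the shh line too the blocked fit recovered 0 of the simulated changes. Those counts held no effect of the pairs, so they do not measure what the block can find in the paired shh libraries. How far the 0 for the shh line can be relied on was not tested.

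With an estimated correlation, a version of little power with 6 libraries, 0 lists were called in each of the 6 comparisons. At the preset correlation whole eyes, RPE, retina, sclera with choroid, the bmp4 line and the shh line had 22, 10, 3, 12, 8 and 10. In the same order fry called 0, 0, 4, 0, 2 and 0. Genes called in the same direction with DESeq2 numbered 292 in whole eyes and RPE, 622 in whole eyes and retina, 401 in whole eyes and sclera with choroid, 624 in RPE and retina, 676 in RPE and sclera with choroid, 860 in retina and sclera with choroid, 5 in whole eyes and the bmp4 line, and 6 in RPE and the bmp4 line. Among genes with a mean log2 CPM of at least 1, whole eyes and RPE shared 17.

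Directions turned for 2 genes that were not called. The lrp2b change in retina was −0.06 without wild-type replicate 12 and −0.24 without mutant replicate 11, within a range of −0.244 to 0.348 over the libraries left out. The LRP2 change in sclera with choroid was −0.09 and −0.15 without wild-type replicates 11 and 13, −0.25 without mutant replicate 11, and −0.013 in the fit of all 24 libraries, within a range of −0.251 to 0.344 over the libraries left out. Over named genes, leaving out a library kept 1371 values on their side of the threshold, moved 622 out of it and turned 5. DESeq2 kept 328, with 3 lost and 2 gained, limma kept 267 and lost 42, RLE scaling kept 359 and lost 3, and no filter kept 351 and lost 11. The fit of all 24 libraries kept 190, lost 95 and turned 1, and the replicate block kept 262 and lost 71, of which 33 were in sclera with choroid, 27 in RPE, 10 in retina and 1 in whole eyes. Depth limits low genes most: at these totals a floor of 3 counts over a group is near 0.04 CPM.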

Other observations

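The test of a shared time of day, the 3 tests of the shh library numbered 13 and the set of genes with large changes in several tissues were chosen only after the results were seen. The other tests were chosen before their own results were seen, but all predictions were written after the main comparisons had first been run.

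Among mutant tissues, 134 genes were called and changed more than 4-fold in the same direction in at least 2 of RPE, retina, and sclera with choroid, 61 higher and 73 lower, 30 of them called so in all 3, and 94 had only a clone name or an identifier. Other alleles in the background of the mutant line are a candidate explanation. These genes varied more between larval control libraries than 10000 matched random sets, at percentile 100 (median SD 0.675 against 0.377), but only 105 of the 134 (78.4%) were measured there, so the test is void. None of the placed genes lay among the tested neighbours of lrp2 (odds ratio 0, 95% interval 0 to 14.7), and with 58 (43.3%) placed that test is void as well. An effect of lrp2 itself and other alleles cannot be told apart with these data, because genotype and family are not separated in the labels.

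Clock genes of mutants may differ because of collection at another time of day. Their fold changes correlated between the 4 tissues with a mean of 0.804 across genes, at the 97.03 percentile of matched random sets, just under the limit set for it, so it stays open, as does an effect of lrp2 on the clock. A correlation of −0.658 (95% interval −0.771 to −0.522) between the lrp2 effect and the wild-type difference of sclera with choroid from retina decides nothing on carry-over, because the same wild-type sclera libraries enter both sides, so carry-over of other tissues stays open too.

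The shh library numbered 13 stood apart from its group. Its deviation fell with gene length (rank correlation −0.397 over 19075 genes, against −0.078 to 0.081 in the 3 controls; the 0.309 and 0.361 of the other transgenic libraries are no independent values, since each was compared with a mean that includes this library), consistent with a loss of long transcripts. A control library under a wrong label is argued against, since SHH (ENSDARG00000068567) was at 47.1 CPM there and at most at 16.95 CPM in controls. More tissue of another kind stays open: ribosomal proteins deviated by 1.71, oxidative phosphorylation by 1.39 and lens by 1.5, and the smaller of the first pair lay below lens by a difference of −0.114 (95% interval −0.283 to 0.141). No biological explanation was tested for a single library.

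Splits of 3 against 3 libraries make 10, too few for a share under 0.05. The real splits called 200, 289, 3909 and 1404 genes in whole eyes, RPE, retina, and sclera with choroid, 22 in the bmp4 line, 15737, 16744 and 10528 between wild-type tissues and 4 between the larval controls, where the highest other split called 0 in each. In each of these 1 split gave as many. In the shh line the real split called 0, the highest other 1, and 10 of 10 gave as many. With the block, the bmp4 line had 609 genes and the highest of the other 3 splits that part all pairs 0, and 4 splits are too few as well. For gene lists the real splits called 22, 10, 3, 12, 8 and 10 in the order of whole eyes, RPE, retina, sclera with choroid, bmp4 and shh, the highest others 19, 22, 14, 21, 20 and 18, and 1, 10, 10, 10, 7 and 8 of 10 splits gave as many. In the paired larval lines the highest others part 1 pair only; the other 3 splits that part all pairs called 6, 8 and 7 lists for bmp4 and 9, 12 and 8 for shh, again too few splits for a share under 0.05. Whether a structure of the libraries or too low a preset correlation between genes gave the list calls of other splits was not tested.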
